A study of Mus musculus with 10 samples.

How the data were processed

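Polyadenylated RNA of mouse OT-I CD8 T cells from spleen and lymph node was sequenced on an Illumina HiSeq from stranded mRNA libraries, per the labels. The deposited values are raw counts per gene, 1 file per sample, and deepTools, STAR, featureCounts and DESeq2 with the GRCm38 build are named in the submitters' processing notes. Those notes give no roles or settings, and tool versions, annotation release and strand setting are not given in the sources used here. The values are whole numbers with sums that differ between samples. Of 53465 genes in the files, 53274 were matched by identifier to GENCODE M21 for symbols and coordinates, and the 191 without a match held at most 0.02% of a library's counts. Samples were grouped by the labels into d5 and d9 in 1 mM glucose with or without 5 mM acetate, giving 4 groups and 10 samples. All 10 samples of the deposited files were used.

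Analysis used R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and sva 3.50.0. Counts were scaled by TMM and filtered with filterByExpr by group, which kept 13182 genes. The 4 group means were fitted with the edgeR quasi-likelihood model (robust, 6 residual degrees of freedom, no covariates). The 5 comparisons were tested with Benjamini-Hochberg adjustment at an adjusted p of 0.05: acetate at each day, d9 against d5 in each acetate state, and the difference of the acetate effects. The biological coefficient of variation was 0.161. SE is the absolute log2 fold change divided by the square root of F. Each comparison was also tested over 41 gene lists, of which those with at least 5 tested members were used, with limma camera at a preset correlation of 0.01. Camera with a correlation estimated per list and fry were run as alternatives. Members of a list were counted past the threshold over all genes and with p-values adjusted over the list alone. The tests, gene lists, comparisons, first set of alternatives and rule for named genes were fixed before the data were examined.

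Named genes followed a rule. Per comparison these were the 10 protein-coding genes with the highest and the 10 with the lowest log2 fold change among those past the threshold, with mean log2 CPM of at least 1 and no overlap between the groups' libraries. For d9 against d5 with acetate and for the difference of acetate effects 5 were taken per direction. Where fewer than 5 passed in a direction, genes of smallest p were added until 5 and are given as not past the threshold. A set of cytokine, granule and acetyl-CoA synthetase genes was always named. Up to 4 members past the threshold were named for fixed lists and lists past camera, or the 2 of smallest p where none passed. Where a group held only zero counts, a floor of 3 counts over the group gave a lower bound of the fold.

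The gene tests were repeated with DESeq2 size factors, library size only, no filter beyond 1 count, a filter of 2 CPM in 2 samples, the DESeq2 Wald test, limma-voom, a fit on only the libraries compared, a minimum change of 1.2-fold (glmTreat), a block for the replicate number, and leaving out each library. The list tests were repeated with DESeq2 size factors, no filter, the block and leaving out each library. Alternatives chosen after seeing the data were the share of counts on ribosomal protein genes as a covariate, 1 surrogate variable as a covariate, removal of transcript length and GC trends (splines, 5 degrees of freedom), and leaving out 2 d9 libraries, of which the last 2 were also applied to the lists. The scripts were tested on simulated data drawn from the real means and library sizes, with 200 genes changed among 13182. At 1.5-, 2- and 4-fold, 17.9, 68.7 and 92.4% of changed genes were recovered for acetate at d9, and 5.97, 28.4 and 89.4% at d5. Without acetate 14.9, 53.7 and 84.8% were recovered for d9 against d5, with acetate 17.9, 68.7 and 77.3%, and for the difference of acetate effects 1.49, 13.4 and 72.7%. Unchanged genes were called too: 10 beside 119 changed ones for acetate at d9 and 5 beside 82 at d5. For d9 against d5 there were 9 beside 102 without acetate and 7 beside 109 with it, and 3 beside 58 for the difference. Simulated noise was independent between genes, around 1 mean per gene over all groups before the changes. With fewer genes changed than 200, or with deviations shared between libraries, recovery in the real data can be lower. Depth was 16.59 to 24.66 M counts per sample. The outlier test needs groups of at least 4 samples and was not applied. A 25 mM glucose arm is not among the deposited samples, so no comparison with unrestricted cells was made. Some single-gene values are not reported here.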

Results

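Polyadenylated RNA was sequenced from mouse OT-I CD8 T cells, whose transgenic receptor recognises an ovalbumin peptide. The cells were activated with peptide and interleukin-2 in 25 mM glucose and moved to 1 mM glucose after 3 days. Restriction lasted 24 h in the samples labelled d5 and 120 h in those labelled d9, with or without 5 mM sodium acetate for the last day. At d5 the last day was the whole restriction, while at d9 acetate came after earlier restriction without it. Activation for 3 days plus restriction for 1 or 5 days does not add up to the labelled day 5 or 9, and the labels do not explain the difference. Cells were restimulated with phorbol ester (PMA) and ionomycin for 4 h before RNA was taken. The 10 libraries formed 4 groups: d5 without acetate (n = 2), d5 with acetate (n = 2), d9 without acetate (n = 3) and d9 with acetate (n = 3). Total counts were 17.05 and 16.59 M in the d5 libraries without acetate and 17.53 and 17.97 M in those with acetate. The d9 libraries held 23.05, 23.93 and 23.67 M without acetate and 23.66, 22.97 and 24.66 M with acetate. Expression is given as CPM scaled by TMM factors, as mean ± SD, and changes as log2 fold changes ± SE. No label says that replicates were separate cultures or animals, so the p-values measure only the spread between these samples, which can be technical.

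Transcripts of the T cell receptor complex and of the CD8 co-receptor were abundant in every group, with Cd8a at 333, 560.0, 589 and 678 CPM in the d5, d5 acetate, d9 and d9 acetate groups. Genes of the lists that mark other lineages varied, with group means of at most 0.448 CPM for Lyz2 and 1.31 CPM for Cd4. Other members of these lists were higher: Zbtb7b at 114 to 148 CPM, Ctla4 at 54.05 to 132 CPM, Zbtb46 at 19.9 to 84.6 CPM, Pecam1 at 16.3 to 49.96 CPM, Fcer1g at 5.38 to 22.9 CPM and Gzma at 117 to 2430.4 CPM. Ighm, an immunoglobulin heavy chain gene, stood at 155, 199.5 and 88.4 CPM in the d5, d5 acetate and d9 groups and at 106 CPM in the d9 acetate group. The first principal component held 66.2% of the variance and separated d5 from d9. The second component held 11.4% and separated the d5 libraries by acetate. At d9, 1 library without acetate (replicate 1) and 1 with acetate (replicate 2) lay apart from the other d9 libraries on the second component. In these 2 libraries 15.5% and 15.2% of counts fell on cytosolic ribosomal protein genes, against 11.2 to 12.8% in the other 4 d9 libraries. Replicates differed by more than sampling noise, with a chi-square of 6.01 to 76.6 per degree of freedom.

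**Figure D1:**
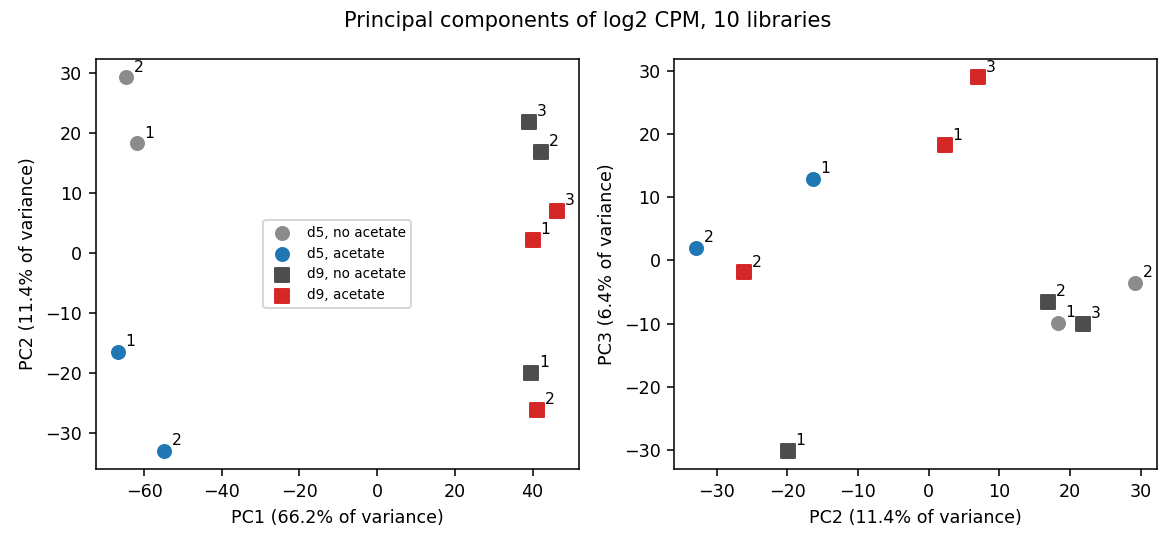
Principal components of log2 CPM for the 10 libraries, with 1 point per library, the replicate number beside it and the share of variance on each axis. The first component (66.2%) separates d5 from d9, and d9 replicate 1 without acetate and d9 replicate 2 with acetate lie at -19.9 and -26.1 on the second.

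Acetate against no acetate at d9 addressed what acetate changes after 120 h of low glucose, in a series titled around effector function under glucose restriction. Il10, which encodes the cytokine interleukin-10, rose from 25.4 ± 4.96 to 95.0 ± 19.0 CPM (SD, n = 3 each), a 3.74-fold change (log2 1.90 ± 0.17, SE). Csf2, which encodes the cytokine GM-CSF, rose from 127 ± 6.79 to 293 ± 27.2 CPM (n = 3 each), a 2.30-fold change. Both genes were higher in 3 of 3 acetate libraries than in any d9 library without acetate. The 2 other genes past the threshold, chosen after their values were seen, encode long intergenic non-coding RNAs. Gm17767 rose from 7.399 ± 0.646 to 20.2 ± 4.77 CPM (log2 1.45 ± 0.18), and Gm36723 rose from 9.22 ± 0.529 to 20.5 ± 2.16 CPM (log2 1.15 ± 0.14). All 4 genes were also past the threshold and higher with acetate at d5, where independent calls would share 0.0264 genes by chance. The calls were not independent, since both tests used the same estimate of each gene's spread, so that value is not their chance level. In GRCm38 coordinates, Il10 (ENSMUSG00000016529) lies on chromosome 1, 131019845 to 131024974, Csf2 (ENSMUSG00000018916) on chromosome 11, 54247271 to 54249667, Gm17767 on chromosome 1, 51507086 to 51596718, and Gm36723 on chromosome 12, 25303940 to 25471979. Exons of Csf2 overlap Gm12223 on the opposite strand, and the strand setting of the counting is not given in the sources used here, so reads of this pair could not be told apart.

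By the edgeR quasi-likelihood test with Benjamini-Hochberg (BH) adjustment, 4 of 13182 genes passed at d9, all higher, and 2026 had an unadjusted p under 0.05. The BH-adjusted p by edgeR was 0.00473 for Il10, 0.00473 for Csf2 and 0.0242 for each of Gm17767 and Gm36723. The count was 18 without d9 replicate 1 and 2 without d9 replicate 2, both of the group without acetate. Without d9 replicate 3 of that group edgeR called 0 genes (1319 at an unadjusted p under 0.05), with adjusted p = 0.0597 for Il10 and 0.0717 for Csf2. With length and GC trends removed 62 genes passed, of which 75.8% were higher. On all libraries DESeq2 called 335 genes and limma-voom 4, and over 20 alternatives the adjusted p of Il10 ranged from 5.37e-18 to 0.117.

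Among the 22 effector cytokines and chemokines tested, 2 rose over all genes tested and 14 rose when p-values were adjusted over the list alone, none fell, and 20 had a positive log2 change. Examples that did not pass over all genes were Ifng, which encodes interferon-gamma, at 558 ± 16.8 without and 921 ± 141 CPM with acetate (log2 0.72 ± 0.13; edgeR quasi-likelihood, BH-adjusted p = 0.0833), and Tnf at 426 ± 14.8 and 665 ± 107 CPM (log2 0.64 ± 0.13; edgeR adjusted p = 0.0991). Il2, the T cell growth factor, stood at 30.1 ± 6.35 and 68.9 ± 15.7 CPM (log2 1.19 ± 0.23; edgeR quasi-likelihood, BH-adjusted p = 0.0886). Il3, a haematopoietic cytokine, stood at 2.88 ± 0.479 and 11.2 ± 3.74 CPM (log2 1.96 ± 0.30; edgeR quasi-likelihood, BH-adjusted p = 0.0674). The list's median log2 change was 0.63, and it was higher than other genes by camera with a preset correlation (adjusted p = 1.70e-12), with adjusted p = 0.0511 with an estimated correlation. The tests over the list alone called from 11 to 16 members under the alternatives tried. Exons of Ifng overlap Gm49751 on the same strand, so its count is uncertain.

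Of the 22 cytotoxic granule genes, none passed over all genes and 6 rose adjusted over the list alone, a number that was 11 without d9 replicate 1 of the group without acetate. Gzmb, which encodes the protease granzyme B, stood at 5039 ± 997 without and 10609 ± 1229.8 CPM with acetate (log2 1.07 ± 0.16; edgeR quasi-likelihood, BH-adjusted p = 0.0674). Gzmc stood at 766 ± 153 and 1810.5 ± 289 CPM (log2 1.24 ± 0.21; edgeR quasi-likelihood, BH-adjusted p = 0.0759). Prf1, which encodes the pore-forming protein perforin, stood at 459 ± 52.8 and 619.6 ± 20.3 CPM (log2 0.43 ± 0.20; edgeR quasi-likelihood, BH-adjusted p = 0.337). Granzyme genes are similar paralogs in a cluster, so reads can be split between them and their single values are uncertain. The list was higher by camera (median log2 0.42; adjusted p = 2.04e-04), with adjusted p = 0.414 with an estimated correlation.

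**Figure D2:**
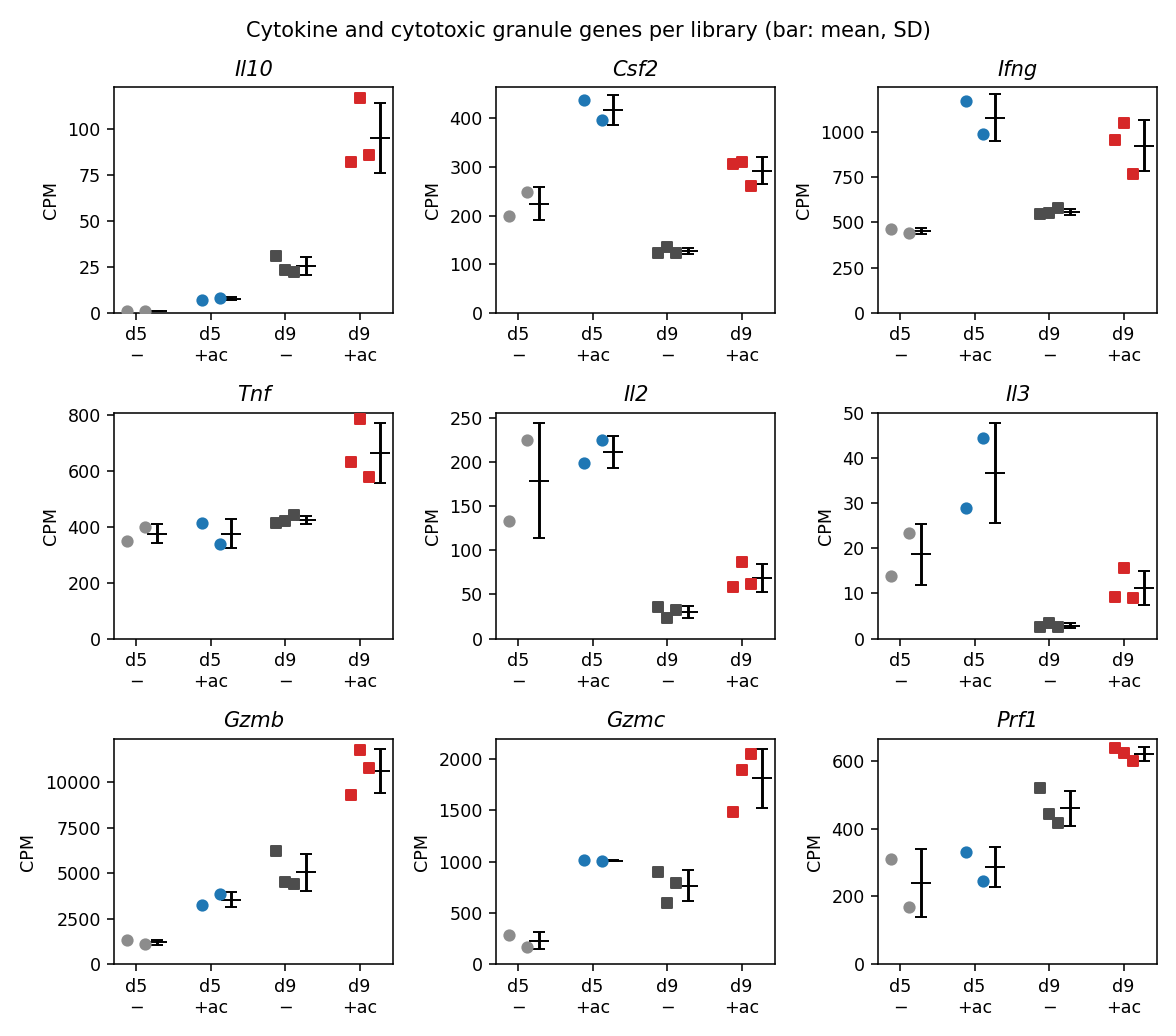
CPM of 9 cytokine and cytotoxic granule genes in each library (points), with the mean and SD of each group beside them, for d5 and d9 without (−) and with (+ac) acetate. At d9, Il10 rose from a mean of 25.4 to 95.0 CPM with acetate and Csf2 from 127 to 293 CPM, and Tnf was at 375 and 376 CPM at d5.

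None of the 19 naive and memory T cell genes passed over all genes at d9 and 4 rose adjusted over the list alone, among them the co-stimulatory receptor gene Cd27 at 39.9 ± 2.71 and 70.6 ± 12.7 CPM and the survival gene Bcl2 at 49.0 ± 2.63 and 73.7 ± 8.15 CPM. This list was higher by camera (adjusted p = 4.92e-04; adjusted p = 0.414 with an estimated correlation). Of the 22 effector differentiation genes, 4 rose over the list alone and 0 over all genes by edgeR, with the transcription factor gene Irf8 at 449.5 ± 19.5 and 1040.4 ± 355 CPM. The list was higher by camera (adjusted p = 3.66e-04; adjusted p = 0.151 with an estimated correlation). Of the 38 immediate early genes that stimulation induces, 5 rose over the list alone, including Fosl2 at 82.9 ± 11.8 and 235 ± 172 CPM, with 432 CPM in acetate replicate 3 against 121 and 151 CPM in the other 2, and camera placed the list higher (adjusted p = 2.16e-04; adjusted p = 0.430 with an estimated correlation). None of the 19 inhibitory receptors and exhaustion regulators passed over all genes or over the list alone, and 16 had a positive change, with Nr4a1 at 121 ± 27.4 and 407 ± 326 CPM. Camera placed that list higher (median log2 0.36; adjusted p = 0.00132; adjusted p = 0.0973 with an estimated correlation).

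Of the 25 cholesterol synthesis genes, 23 had a negative log2 change with acetate at d9, 0 passed over all genes by edgeR and 5 fell adjusted over the list alone. Insig1, a sterol-sensing regulator, stood at 52.8 ± 1.27 and 37.5 ± 3.33 CPM (log2 -0.49 ± 0.10; edgeR quasi-likelihood, BH-adjusted p = 0.0991). The list was lower by camera (median log2 -0.18; adjusted p = 4.04e-05; adjusted p = 0.0511 with an estimated correlation). Of the 17 NRF2 antioxidant response genes, 5 fell over the list alone and none over all genes, with the ferritin gene Fth1 at 885 ± 92.1 and 624 ± 37.2 CPM, and the list was lower by camera (adjusted p = 0.00480; adjusted p = 0.135 with an estimated correlation). Of the 19 hypoxia response genes, 18 had a positive change and none passed over all genes or over the list alone, and the list was higher by camera (median log2 0.66; adjusted p = 1.17e-04; adjusted p = 0.430 with an estimated correlation). Vegfa, an angiogenic growth factor gene of that list, stood at 118 ± 20.7 and 185 ± 47.5 CPM. None of the 21 genes of acetate uptake and acetyl-CoA metabolism passed over all genes or over the list alone (median log2 -0.09; camera adjusted p = 0.525). The acetyl-CoA synthetase gene Acss2 stood at 19.9 ± 4.88 and 14.9 ± 0.978 CPM (log2 -0.42 ± 0.17), and Acss1 at 5.71 ± 1.07 and 5.38 ± 0.265 CPM. Exons of Acss2 overlap Acss2os, Ggt7 and Gss on the opposite strand, so its count is uncertain.

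In all, camera placed 18 of 35 lists past its threshold at d9, 12 higher and 6 lower, and 0 with an estimated correlation, and fry called 6. Of the 18, 9 stayed past it without each single d9 library, but without acetate replicate 3 the mean log2 change was 0.16 against 0.36 for immediate early genes and 0.41 against 0.65 for hypoxia response genes. Among these 9, cytotoxic granule (adjusted p = 0.0933), naive and memory T cell (0.123), immediate early (0.206) and hypoxia response genes (0.214) were not past fry. The other 9 lost the camera threshold without at least 1 d9 library, named here by its group and replicate. The unfolded protein response (adjusted p = 0.00863, 0.430 with an estimated correlation) and heat shock response (0.0139, 0.152) lost it without acetate replicate 3 (0.0792 and 0.0889). Nuclear oxidative phosphorylation genes (adjusted p = 1.17e-04, 0.671 with an estimated correlation) and autophagy and lysosome genes (0.00285, 0.430) lost it without replicate 1 of the group without acetate (0.0502 and 0.0547). Ribosome biogenesis genes (adjusted p = 0.0103, 0.430 with an estimated correlation) lost it without that library (0.150) and without acetate replicate 2 (0.0994). G2/M genes (adjusted p = 2.04e-04, 0.658 with an estimated correlation) lost it without replicate 3 of the group without acetate (0.0967) and without acetate replicate 1 (0.0870). Glycolysis (adjusted p = 0.0365, 0.772 with an estimated correlation) lost it without replicates 2 and 3 of the group without acetate (0.0514 and 0.444) and without acetate replicates 2 and 3 (0.524 and 0.204). Mitochondrially encoded mRNAs (adjusted p = 0.0468, 0.430 with an estimated correlation) lost it without replicates 2 and 3 of the group without acetate (0.0514 and 0.138) and without acetate replicates 1 and 3 (0.227 and 0.157). NK cell markers (adjusted p = 0.0349, 0.430 with an estimated correlation) lost it without replicates 2 and 3 of the group without acetate (0.104 and 0.133) and without acetate replicates 1 and 2 (0.0649 and 0.0994). Mitochondrially encoded mRNAs also lost it with length and GC trends removed (0.228), and NK cell markers without a low-count filter (0.195).

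Acetate against no acetate at d5 asked the same after 24 h of restriction. Il10 rose from 1.16 ± 0.00691 to 7.71 ± 0.842 CPM (SD, n = 2 each; log2 2.72 ± 0.29), Ifng rose from 451 ± 17.01 to 1077 ± 129 CPM (log2 1.26 ± 0.16), and Csf2 rose from 224 ± 34.5 to 417 ± 30.4 CPM (log2 0.89 ± 0.14). Gzmb rose from 1214 ± 141 to 3549 ± 412 CPM (log2 1.55 ± 0.20), and Gzmc from 229 ± 81.4 to 1009 ± 3.85 CPM (log2 2.14 ± 0.26). Tnf stood at 375 ± 33.8 and 376 ± 52.0 CPM (log2 0.00 ± 0.16), Il2 at 179 ± 65.4 and 212 ± 18.0 CPM, and Prf1 at 239.7 ± 101 and 288 ± 59.5 CPM, none of them past the threshold. Other genes that rose included Pdzk1ip1 (log2 2.22 ± 0.40), the NAD-consuming ectoenzyme gene Cd38 (1.96 ± 0.40), Cdh1, which encodes E-cadherin (1.77 ± 0.30), and the activating receptor gene Cd226 (1.75 ± 0.33). Genes that fell included Smtn (log2 -2.42 ± 0.32), the chemokine receptor gene Cxcr3, from 39.5 ± 1.64 to 9.53 ± 2.69 CPM (-2.05 ± 0.24), the cytoskeletal linker gene Vcl (-1.89 ± 0.28) and Mmp10 (-1.84 ± 0.28).

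By the edgeR quasi-likelihood test with BH adjustment, 201 genes passed at d5, 87 higher and 114 lower, of which 43 and 60 changed by more than 2-fold. The BH-adjusted p by edgeR was 0.00714 for Il10, 0.00826 for Cxcr3, 0.00976 for Ifng, 0.0112 for Gzmb and 0.0210 for Csf2, against 0.991 for Tnf. The count was 10 without d5 replicate 1 of the group without acetate. It was 0 by edgeR without its replicate 2, without acetate replicate 1 and without acetate replicate 2, with 1458, 1872 and 1490 genes at an unadjusted p under 0.05. Each of these fits leaves a group with 1 library, which is assumed to vary like the other groups. No call of a named gene at d5 held in all 4 of these fits. Among the lists that mark other lineages, 1 B cell, 1 CD4 T cell and 1 NK cell marker rose with acetate at d5 and 1 monocyte and macrophage marker fell, and 0 passed at d9 (edgeR, adjusted over all tested genes).

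Of the 22 effector cytokines and chemokines, 4 rose at d5 over all genes, Il10, Ifng, Csf2 and Lta (log2 0.66 ± 0.13), and none fell. Adjusted over the list alone, 12 rose and 1 fell. The list was higher by camera (median log2 0.55; adjusted p = 6.55e-05), with adjusted p = 0.603 with an estimated correlation. The number past over the list alone, 13, was 7 and 6 without d5 replicates 1 and 2 of the group without acetate, and 7 and 6 without acetate replicates 1 and 2. Of the 22 cytotoxic granule genes, 3 rose over all genes, Gzmc, Gzmb and the serine protease inhibitor gene Serpinb6b (log2 1.06 ± 0.21), and 8 rose adjusted over the list alone, a number that was 5 without replicate 2 of the group without acetate and 5 without acetate replicate 2. Camera placed this list higher (median log2 0.65; adjusted p = 6.55e-05), with adjusted p = 0.603 with an estimated correlation. Its mean of 0.68 was 1.12 without d5 replicate 1 of the group without acetate and 0.38 without acetate replicate 1. Among 19 inhibitory receptors and exhaustion regulators, 3 rose, Cd38, Cd244a (log2 1.37 ± 0.24) and the ectonucleotidase gene Entpd1 (log2 1.09 ± 0.22). That list was not past camera (adjusted p = 0.312), and its median (-0.00) and mean (0.26) differed in sign. Of the genes of acetate uptake and acetyl-CoA metabolism, 1 fell, the aromatic amino acid transporter gene Slc16a10 (log2 -1.16 ± 0.23), and the list had a median of -0.02 and camera adjusted p = 0.794.

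Camera placed 9 of 35 lists past its threshold at d5, 8 higher and 1 lower, and 0 with an estimated correlation, and fry called 5. The 7 lists other than cytokines and granule genes each lost it without 2 libraries, named here by group and replicate. Glycolysis, in which Eno3 rose (log2 1.22 ± 0.25), had adjusted p = 0.0257 (0.760 with an estimated correlation), and 0.0582 and 0.517 without replicate 2 of the group without acetate and acetate replicate 2. For the same pair left out, the unfolded protein response, in which Hsp90b1 rose (log2 0.70 ± 0.14), went from adjusted p = 0.0257 (0.603 with an estimated correlation) to 0.0781 and 0.103. Cytosolic ribosomal proteins went from adjusted p = 0.0260 (0.839 with an estimated correlation) to 0.166 and 0.502. The lower list, G2/M genes, went from adjusted p = 0.00388 (0.760 with an estimated correlation) to 0.110 and 0.0748. Ribosome biogenesis genes, in which Gnl3 (log2 0.65 ± 0.14) and Wdr43 (log2 0.65 ± 0.12) rose, had adjusted p = 0.0128 (0.603 with an estimated correlation), and 0.252 and 0.175 without replicate 1 of the group without acetate and acetate replicate 2. With these same 2 libraries out in turn, the hypoxia response went from adjusted p = 0.0257 (0.760 with an estimated correlation) to 0.281 and 0.487. NK cell markers, in which Klrb1c rose (log2 1.86 ± 0.31), had adjusted p = 0.0279 (0.603 with an estimated correlation), and 0.110 and 0.136 without replicate 2 of the group without acetate and acetate replicate 1. The share of counts on ribosomal protein genes was 12.04 and 10.9% without and 11.9 and 14.1% with acetate, and that on mitochondrial genes was 0.797 and 0.781% without and 1.12 and 1.101% with acetate. The hypoxia response had adjusted p = 0.0514 with length and GC trends removed.

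**Figure D3:**
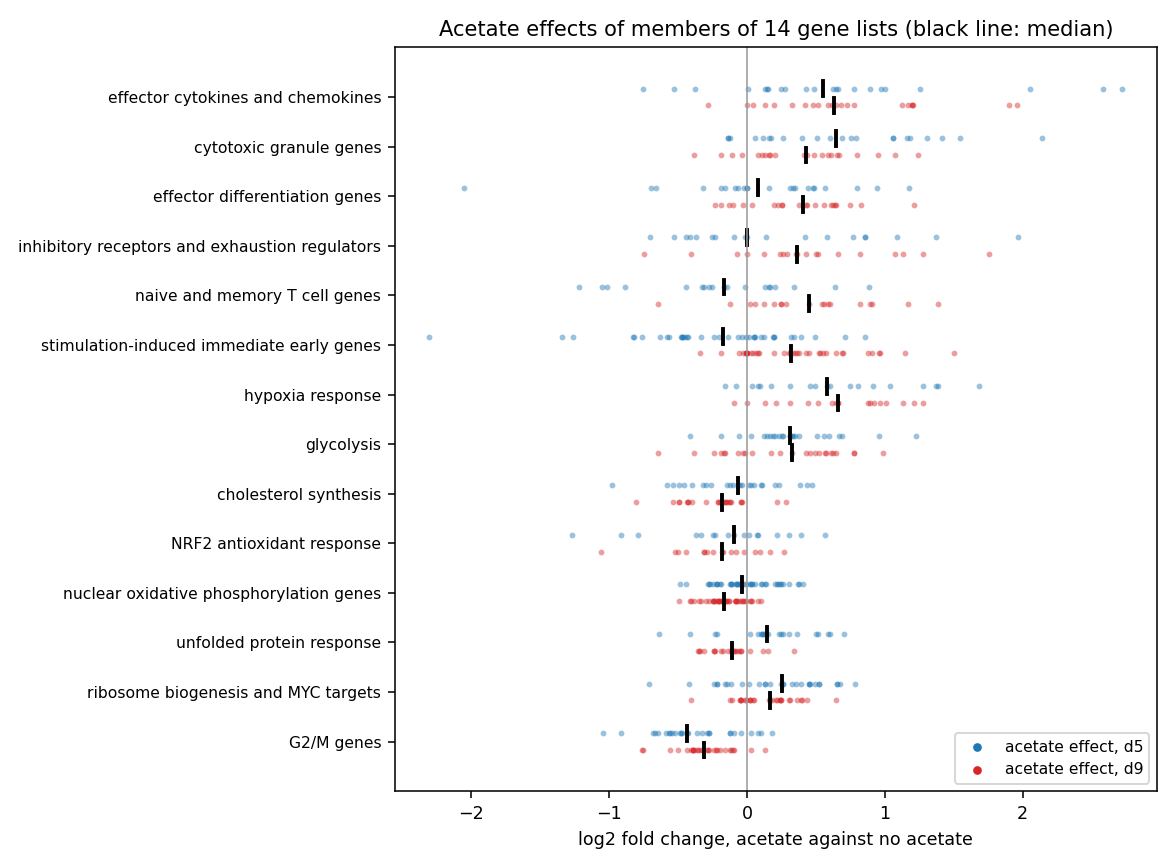
Log2 fold change with acetate at d5 and at d9 for each tested member (points) of 14 gene lists, with the list's median as a black line. Effector cytokines and chemokines have medians of 0.55 at d5 and 0.63 at d9, and cholesterol synthesis -0.07 and -0.18.

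The difference of the acetate effects between d9 and d5 addressed whether the response to acetate differs between the days. Duration of restriction could not be told apart from whether acetate was present from its start, as it was only at d5. Jun, an AP-1 transcription factor gene, stood at 36.2 ± 6.08 and 14.3 ± 2.25 CPM without and with acetate at d5 (n = 2 each) and at 48.3 ± 0.949 and 62.8 ± 9.04 CPM at d9 (n = 3 each), a log2 difference of 1.72 ± 0.23 (edgeR quasi-likelihood, BH-adjusted p = 0.0648). Tmem171 had a difference of 1.77 ± 0.25 (edgeR quasi-likelihood, BH-adjusted p = 0.0648), and the lipase gene Mgll one of -1.43 ± 0.22 (edgeR quasi-likelihood, BH-adjusted p = 0.0780). For Ifng the difference was -0.53 ± 0.20, for Tnf 0.64 ± 0.21, for Il2 0.95 ± 0.36 and for Gzmb -0.47 ± 0.26, with BH-adjusted p by edgeR of 0.552, 0.483, 0.544 and 0.700. The edgeR quasi-likelihood test called 0 genes, with 1015 at an unadjusted p under 0.05, limma-voom called 0 and DESeq2 102. The edgeR count was 1 without d9 replicate 1 of the group without acetate and 1 without d9 acetate replicate 3. Effector cytokines were not past camera (adjusted p = 0.543), while immediate early genes were (mean difference 0.60; adjusted p = 2.04e-06; adjusted p = 0.699 with an estimated correlation).

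Across 13182 genes, which are not independent replicates, the acetate effects at d5 and d9 had a Pearson correlation of 0.272 (jackknife SE over libraries 0.182) and a Spearman correlation of 0.326. Of the 201 genes past the threshold at d5, 165 (82.1%) had the same sign at d9, among them Il10, Csf2, Ifng, Gzmb and Gzmc, against 63.2% of all genes. Of the 87 that rose at d5, 80 had a positive change at d9, and of the 114 that fell, 85 had a negative one. Without the low-count filter the Pearson correlation was 0.0340, and with the stricter filter on CPM it was 0.356.

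Prolonged against acute restriction without acetate compared d9 with d5, which also differ in days of culture and in depth. Any batch that went with the day could not be told apart from it. Genes that drive mitosis fell: all 28 G2/M genes were lower at d9, with the spindle gene Nusap1 from 60.4 ± 4.85 (SD, n = 2) to 4.98 ± 0.476 CPM (n = 3; log2 -3.60 ± 0.16) and the kinetochore gene Cenpf from 22.7 ± 3.36 to 1.71 ± 0.214 CPM (log2 -3.72 ± 0.26). Of the 28 S phase genes, 24 fell, among them the cyclin gene Ccne2 (log2 -3.64 ± 0.27) and the ribonucleotide reductase gene Rrm2 (-2.57 ± 0.30). Granule genes went the other way: 15 of 22 rose and 1 fell, with Gzmb from 1214 ± 141 to 5039 ± 997 CPM (log2 2.05 ± 0.20) and Gzmf from 1.26 ± 0.631 to 59.9 ± 19.0 CPM (5.55 ± 0.36). Gzmd, Gzme and Gzmg rose by log2 5.64, 5.83 and 5.59, but these paralogs are near-identical and their single values are uncertain. Among 22 effector cytokines and chemokines, 3 rose and 10 fell: Il10 rose from 1.16 ± 0.00691 to 25.4 ± 4.96 CPM (log2 4.44 ± 0.27), Il2 fell from 179 ± 65.4 to 30.1 ± 6.35 CPM (-2.57 ± 0.25) and Il3 from 18.7 ± 6.73 to 2.88 ± 0.479 CPM (-2.70 ± 0.32). Ifng and Tnf did not pass, with log2 changes of 0.31 ± 0.14 and 0.18 ± 0.15.

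Interferon-stimulated genes rose in 14 of 21 cases and fell in 1, with the ubiquitin-like modifier gene Isg15 from 1.22 ± 0.151 to 18.4 ± 2.91 CPM (log2 3.91 ± 0.28) and the antiviral GTPase gene Mx1 from 8.45 ± 0.0208 to 57.4 ± 7.87 CPM (2.76 ± 0.19). Of the 31 integrated stress response (ATF4) genes, 20 rose and 2 fell, with Stc2 at log2 1.08 ± 0.22 and the cysteine synthesis gene Cth at -2.88 ± 0.21. Of 20 p53 targets, 12 rose and 3 fell, including Phlda3 (log2 2.59 ± 0.16) and Plk2 (-1.44 ± 0.11). Of 29 autophagy and lysosome genes, 11 rose and none fell, including the lysosomal protease gene Ctsd (log2 1.71 ± 0.19) and the autophagy receptor gene Sqstm1 (1.41 ± 0.12). Acss2 rose from 5.00 ± 0.523 to 19.9 ± 4.88 CPM (log2 1.99 ± 0.21), while Acss1 stood at 5.29 ± 0.615 and 5.71 ± 1.07 CPM. Among inhibitory receptors and exhaustion regulators, 4 rose and 7 fell, with Entpd1 (log2 3.19 ± 0.20) and the transcription factor gene Eomes (2.37 ± 0.19) higher, and the receptor gene Btla (-3.08 ± 0.28) and the transcription factor gene Tox (-2.50 ± 0.25) lower. Outside these lists, genes that rose included Tgm2 (log2 6.90 ± 0.41) and the activin-like receptor gene Acvrl1 (6.30 ± 0.38), while Mmp10 (-6.56 ± 0.31), the cytokine gene Il1a (-6.26 ± 0.23) and the receptor gene Slamf6 (-5.43 ± 0.31) fell.

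By the edgeR quasi-likelihood test with BH adjustment, 4895 of 13182 genes passed without acetate, 2096 higher and 2799 lower. The BH-adjusted p by edgeR was 1.15e-06 for Nusap1, 2.91e-06 for Il10, 3.63e-05 for Gzmb and 7.00e-05 for Acss2. The count was 2946 without d5 replicate 1 and 2829 without d5 replicate 2, each leaving 1 library that is assumed to vary like the other groups. Prf1, from 239.7 ± 101 to 459 ± 52.8 CPM (log2 0.94 ± 0.23; edgeR quasi-likelihood, BH-adjusted p = 0.00922), lost its call without d5 replicate 2 (adjusted p = 0.0748). Higher genes made up 42.8% of the calls, 32.3% when scaled by library size only, which moves the median log2 change of all genes to -0.11, and 53.2% with trends in transcript length and GC content removed. With these trends removed 4977 genes passed, of which only 3573 were among the 4895 and in the same direction.

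Camera placed 11 of 35 lists past its threshold without acetate, 8 higher and 3 lower, and 0 with an estimated correlation, and fry called 14. Lower lists were G2/M genes (median log2 -2.44; adjusted p = 3.24e-17; adjusted p = 0.381 with an estimated correlation) and S phase genes (-1.12; adjusted p = 1.25e-08; adjusted p = 0.441 with an estimated correlation). Higher lists included cytotoxic granule genes (1.08; adjusted p = 9.47e-07; adjusted p = 0.344 with an estimated correlation) and interferon-stimulated genes (0.90; adjusted p = 9.47e-07; adjusted p = 0.1002 with an estimated correlation). ATF4 genes (adjusted p = 2.59e-04), p53 targets (0.00501) and autophagy and lysosome genes (0.00433) were also higher, with adjusted p = 0.344, 0.441 and 0.441 with an estimated correlation. Effector cytokines (adjusted p = 0.191) and inhibitory receptors (0.587) were not past camera. Mitochondrially encoded mRNAs fell in 7 of 8 cases, with mt-Nd1 at log2 -1.42 ± 0.14 and mt-Cytb at -1.41 ± 0.17 (camera adjusted p = 5.97e-04; adjusted p = 0.344 with an estimated correlation). With length and GC trends removed that call was lost (mean -0.24 against -1.30; adjusted p = 0.451), as was that of mt-Nd1 (log2 -0.40; edgeR quasi-likelihood, BH-adjusted p = 0.0879), while mt-Cytb kept its call (log2 -0.56; edgeR quasi-likelihood, BH-adjusted p = 0.00340). Cytosolic ribosomal proteins were higher (5 of 36 rose, 0 adjusted over the list alone; median 0.38; adjusted p = 3.65e-04; adjusted p = 0.751 with an estimated correlation), in groups whose d9 replicate 1 had 15.5% of counts on such genes. Hypoxia response and glycolysis genes, of which 6 of 19 and 9 of 25 rose, had adjusted p = 0.00501 and 0.00814 (0.751 and 0.751 with an estimated correlation), and 0.0566 and 0.0646 without d9 replicate 1. Glycolysis genes had adjusted p = 0.245 with length and GC trends removed.

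The same comparison with acetate in both groups gave 5480 genes by the edgeR quasi-likelihood test with BH adjustment, 2436 higher and 3044 lower. All 28 G2/M genes fell again, with Nusap1 from 64.6 ± 7.78 to 3.93 ± 0.640 CPM (log2 -4.04 ± 0.17), and 24 of 28 S phase genes fell. Of the 22 granule genes, 14 rose and 1 fell, with Gzmb at log2 1.58 ± 0.19 and Prf1 at 1.11 ± 0.23. Il10 rose from 7.71 ± 0.842 to 95.0 ± 19.0 CPM (log2 3.62 ± 0.23), Tnf from 376 ± 52.0 to 665 ± 107 CPM (0.82 ± 0.15) and Acss2 from 4.66 ± 0.174 to 14.9 ± 0.978 CPM (1.67 ± 0.21), and Il2 fell from 212 ± 18.0 to 68.9 ± 15.7 CPM (-1.62 ± 0.25). Of the 21 interferon-stimulated genes, 18 rose and 1 fell, including Isg15 (log2 2.94 ± 0.25). Rsad2 was at 0 in both d5 acetate libraries and at 0.478 ± 0.168 CPM at d9, at least 5.66-fold higher against a floor of 3 counts over the group. With Rsad2 at that bound the list's median was 1.41, as before. Immediate early genes rose in 20 of 38 cases and fell in 4, with Dusp5 (log2 2.48 ± 0.24) and Jun (2.14 ± 0.17) among the former, and 10 of 22 unfolded protein response genes fell and 2 rose, with Hsp90b1 at -1.72 ± 0.13 and Ern1 at 1.73 ± 0.22.

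The BH-adjusted p by edgeR was 8.41e-07 for Nusap1, 3.87e-06 for Il10, 0.00173 for Tnf and 2.12e-05 for Isg15, and the calls of Il10, Tnf and Isg15 held under every alternative tried. The call of Il2 (BH-adjusted p by edgeR 5.79e-04) was lost with length and GC trends removed (0.108). The count was 3106 without d5 acetate replicate 1 and 3619 without d5 acetate replicate 2, each leaving 1 library that is assumed to vary like the other groups. Higher genes made up 44.5% of the calls, 33.9% when scaled by library size only and 51.8% with length and GC trends removed. With these trends removed 5154 genes passed, of which only 3683 were among the 5480 and in the same direction. Camera placed 12 of 35 lists past its threshold, 8 higher and 4 lower, 0 with an estimated correlation, and fry called 18. Adjusted p was 1.80e-15 for G2/M, 2.01e-08 for S phase, 8.81e-05 for granule, 2.26e-08 for interferon-stimulated and 5.04e-04 for immediate early genes, and 0.0152 for the unfolded protein response. With an estimated correlation the adjusted p of these 6 was 0.528, 0.528, 0.528, 0.0542, 0.652 and 0.528. Mitochondrially encoded mRNAs, lower by camera (adjusted p = 0.00247; adjusted p = 0.528 with an estimated correlation), had a mean of 0.24 and adjusted p = 0.939 with length and GC trends removed. Targets of p53 were higher (adjusted p = 0.0132; adjusted p = 0.528 with an estimated correlation).

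Higher by camera, but not without every library, were ATF4 genes (adjusted p = 0.0140, 0.528 with an estimated correlation), hypoxia response (0.00459, 0.780), autophagy and lysosome (0.0220, 0.652) and glycolysis genes (0.0436, 0.859). ATF4 genes had adjusted p = 0.0565 without d9 acetate replicate 2 and 0.580 with length and GC trends removed. Hypoxia response genes had adjusted p = 0.0576 without d5 acetate replicate 1. Autophagy and lysosome genes had adjusted p = 0.0710 without that library and 0.0580 without d9 acetate replicate 2. Glycolysis genes had adjusted p = 0.361, 0.295 and 0.0845 without d5 acetate replicate 1, d9 acetate replicate 2 and d9 acetate replicate 3. Their mean of 0.42 was 0.23 with length and GC trends removed (adjusted p = 0.622), and with DESeq2 size factors their adjusted p was 0.0536.

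**Figure D4:**
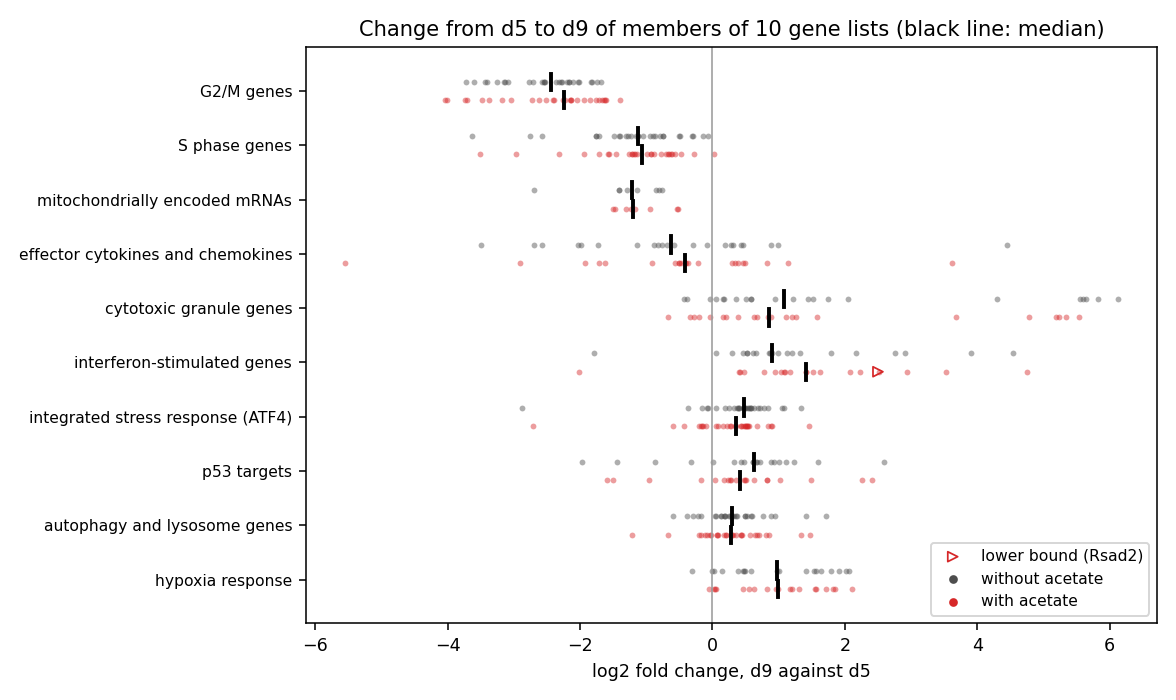
Log2 fold change from d5 to d9, without and with acetate, for each tested member (points) of 10 gene lists, with the list's median as a black line and the open triangle marking the lower bound for Rsad2. G2/M genes have medians of -2.44 and -2.25, and cytotoxic granule genes 1.08 and 0.86, and mitochondrially encoded mRNAs -1.22 and -1.21, with a mean of 0.24 with acetate once length and GC trends are removed.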

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

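The 2 tests of explanations in this part were written down before they were run. For 4 gene lists the acetate effect at d9 differed from that at d5 by a test of the difference itself. No single gene passed that comparison. Immediate early genes had a mean log2 difference of 0.60 with 32 of 38 positive (camera adjusted p = 2.04e-06; adjusted p = 0.699 with an estimated correlation), and 7 rose adjusted over the list alone. Jun had a difference of 1.72 ± 0.23 (edgeR quasi-likelihood, BH-adjusted p = 0.0648) and Fosb one of 3.26 ± 0.80 (edgeR quasi-likelihood, BH-adjusted p = 0.249). Naive and memory T cell genes had a mean of 0.63 with 16 of 19 positive (camera adjusted p = 3.27e-04; adjusted p = 0.699 with an estimated correlation), with Cd27 at 1.26 ± 0.22 and Bcl2 at 0.76 ± 0.18. The unfolded protein response had a mean of -0.28 (camera adjusted p = 1.97e-05; adjusted p = 0.699 with an estimated correlation), with Hsp90b1 at -0.68 ± 0.18. Cytosolic ribosomal proteins had a mean of -0.27 (camera adjusted p = 3.27e-04; adjusted p = 0.965 with an estimated correlation). That last list lost its place without d5 acetate replicate 2 (0.137), d9 replicate 1 without acetate (0.0675) and d9 acetate replicate 1 (0.0976), and the other 3 kept theirs without each library. The mean of naive and memory T cell genes was 0.42 without d5 replicate 2 of the group without acetate. With all libraries, immediate early genes and naive and memory T cell genes were not past fry (adjusted p = 0.358 each). At d9 the libraries differ in their ribosomal protein share, 15.5% and 15.2% in 2 of them.

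The difference in immediate early genes was weighed against 2 technical explanations. At d9 1 acetate library, replicate 3, had high levels of such genes (Fosl2 at 432 CPM). Without it the list's mean difference was 0.41 against 0.60, with 31 of 38 positive and camera adjusted p = 3.84e-05 at the preset correlation. The mean thus rested in part on this library, and in part on the d5 effect, a mean of -0.24. The preset test cannot decide on the rest, since with all libraries the list was not past fry either (adjusted p = 0.358). With length and GC trends removed the mean was 0.56 (camera adjusted p = 1.92e-06 at the preset correlation), so these trends account for little of the mean. The biological explanation, that acetate acts on the response to restimulation differently after long restriction, could apply but was not tested. All 10 libraries were restimulated, so a changed response could not be told apart from a changed level before it. Day also differs in culture time, in depth and in whether acetate was present from the start of restriction. By camera with an estimated correlation the list was not past the threshold (adjusted p = 0.699). That setting also missed the G2/M genes, which all fell from d5 to d9 without acetate (adjusted p = 0.381), so it cannot decide here.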

How the results depend on the processing

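Of 7770 alternative values for named genes and lists, 7024 kept their side of the threshold and, where past it, their direction, 437 fell below it, 299 passed it, 6 moved and 4 reversed. These include values not past the threshold in the main fit, so the share kept does not measure how stable the calls are. Of the named genes called with acetate, 0 of 2 at d9 and 0 of 32 at d5 held under every alternative. The replicate block within day alone left 0 calls at each. Of the gene values 28 changed sign, most of them not past the threshold in either fit, and the cause was not tested where none is given. Counts of genes for acetate at d9 (4), at d5 (201) and for the difference (0) were 197, 578 and 99 without a filter, 335, 786 and 102 with DESeq2, 955, 1076 and 35 with the ribosomal share as covariate, 1214, 1646 and 134 with 1 surrogate variable, and 62, 451 and 22 with length and GC trends removed. Without both d9 libraries of highest ribosomal share the d9 count was 152 and the difference 164. At d5 the count was 1736 on only the compared libraries and 49 with a 1.2-fold minimum, where 8 cytokines were past over the list alone against 13. Leaving out 1 library gave 0 to 18 genes at d9, 0 to 10 at d5, 0 to 1 for the difference, 2829 to 4770 for d9 against d5 without acetate and 3106 to 5698 with it, 6 to 7 cytokines at d5, and 3 to 8 lists at d5. A lone library left in a group is assumed to vary like the other groups. The lists past camera, 18 at d9, 9 at d5, 11 and 12 for d9 against d5 and 4 for the difference, were 0 in each with an estimated correlation. This held even for the G2/M genes, which all fell from d5 to d9, so not passing there does not show that a list was unchanged. By fry 6, 5, 14, 18 and 2 lists passed, of which 6, 3, 8, 10 and 1 were among those past camera. The correlation of acetate effects was 0.0340 without a filter, 0.356 with the stricter filter on CPM and 0.152 to 0.362 without 1 library. With length and GC trends removed, 4 results of d9 against d5 with acetate reversed: Ifng at 0.50 (edgeR quasi-likelihood, BH-adjusted p = 0.0117), mt-Nd3 at 0.29 (0.353), mt-Nd1 at 0.0151 (0.953) and the mean of mitochondrially encoded mRNAs at 0.24 (0.939). At d5, with 2 libraries per group, 28.4% of simulated 2-fold changes were recovered, so changes of that size can be missed.

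No source says that replicate numbers pair the samples, and deviations of same-numbered libraries correlated at 0.0293 at d5 and at -0.139, -0.392 and 0.329 at d9. Between days they correlated at 0.163 and 0.113 without acetate and at 0.163 and 0.221 with it, and across acetate states at -0.0451, -0.131, -0.243 and -0.0849. Since not every same-numbered pair was over 0.1, the numbers were not taken to pair the samples. With the number as a replicate block the counts were 4 at d9, 62 at d5, 4248 and 4556 for d9 against d5 without and with acetate and 0 for the difference. With the block within day they were 0 at d9, 0 at d5 and 0 for the difference. A fit on only the compared libraries was not run for the difference, which uses all 10.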

Other observations

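Several groups of genes changed from d5 to d9 in both directions. Among inhibitory receptors and exhaustion regulators with acetate, 5 of 19 rose and 6 fell over all genes, with Eomes at log2 3.13 ± 0.20, Btla at -3.42 ± 0.27 and Tox at -2.80 ± 0.26 (camera adjusted p = 0.965). Among effector cytokines and chemokines with acetate, 4 rose and 9 fell, with Xcl1, a chemokine gene, at -1.93 ± 0.21 and Tnfsf10, which encodes the death ligand TRAIL, at -2.91 ± 0.22 (camera adjusted p = 0.640). Among genes of acetate uptake and acetyl-CoA metabolism, 3 rose and 4 fell with acetate, including Acss2 at 1.67 ± 0.21 and the thioesterase gene Acot7 at 0.74 ± 0.12, and the list's median (0.02) and mean (-0.03) differed in sign.

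In 2 d9 libraries of different groups, replicate 1 without acetate and replicate 2 with acetate, deviations from the group means correlated at 0.509 across genes, and both had the highest ribosomal protein shares at d9 (15.5% and 15.2%). Tests of this were written down before they were run. If the labels were swapped, replicate 1 would score like an acetate library on the genes past the threshold at d5, but every acetate library scored at least 0.185 above every library without acetate. With length and GC trends removed the correlation was 0.401, so these trends account for at most part of the pattern. No biological explanation was tested, since no group of the design separates these 2 libraries.

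Lars2, which encodes the mitochondrial leucyl-tRNA synthetase, was lower at d9 than at d5 without acetate (log2 -4.42 ± 0.84; edgeR quasi-likelihood, BH-adjusted p = 0.00249). That call was lost without both d9 libraries of highest ribosomal protein share, at a log2 change of -4.12 with fewer libraries (edgeR quasi-likelihood, BH-adjusted p = 0.0648). Its CPM was 1834 and 5588 at d5 without and 2228 and 292 with acetate, and 95.8, 201 and 222 at d9 without and 379, 111 and 160.0 with acetate. Gm42418, a locus that overlaps ribosomal RNA sequence, held 1.86 and 3.83% of counts at d5 without and 4.50 and 0.880% with acetate. At d9 it held 0.161 to 0.469%. Among the d5 libraries both Lars2 and Gm42418 were lowest in acetate replicate 2. A test chosen after these values were seen used the 6 d9 libraries. Lars2 and Gm42418 correlated there with Pearson r of 0.228 (exact permutation p = 0.678) and Spearman 0.143 (exact permutation p = 0.803). Pearson r was -0.644 without the 2 farthest libraries. The d5 libraries, in which both ranged most widely, were left out. The test therefore cannot decide whether ribosomal RNA reads were assigned to Lars2, and the fall is not shown to be one of Lars2 mRNA. The other 16 mitochondrial synthetases had a median log2 change of -0.068 (from -0.76 to 0.54), so Lars2 did not fall with them.

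With the 6 d9 libraries split into 2 groups of 3 in every way, 1 of 10 splits, the real one, gave as many as 4 genes and the highest of the others gave 0, which is too few splits for a share under 0.05. In repeats chosen after these values were seen, with 1 surrogate variable 2 other splits gave 575 and 581 genes against 1214, and with the ribosomal share as covariate the others gave 0 against 955.

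A hypothesis written down before its test was that acetate at d9 reverses the change from d5 to d9. The effects correlated across genes with Pearson r of 0.0562. In 40 simulated data sets that kept each day's mean and had no acetate effect, r ranged from -0.0245 to 0.0205. A reversal would give a negative r, and a strong one was not seen. Real libraries can share deviations across genes, with a correlation of 0.509 between a d9 library without and one with acetate. The like correlation of the acetate effects at d5 and d9 had a jackknife SE over libraries of 0.182. An r this small cannot be told from 0 or from a modest negative value, so the test cannot decide on a modest reversal.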
